A study of Drosophila melanogaster with 24 samples.

How the data were processed

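Messenger RNA was measured in whole animals of 4 Drosophila melanogaster strains at 2 stages, with 3 biological replicates per strain and stage. Per the labels' protocols, larvae were raised at 25 °C in food with 0.05% bromophenol blue, a dye that shows in the larval gut, and about 120 mg of frozen animals, 60 to 80 individuals, were ground for each replicate. RNA of different strains was extracted independently, and the labelled samples were hybridised by the array maker's service on single-colour (cy3) NimbleGen arrays, per the labels' protocols. The labels name the larval stage with the number 18 and define it as late in the last larval instar; the sex of the animals was not given in the sources used here. The strain and stage of each sample were taken from the labels, and the replicate number from the last digit of the sample title.

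The authors deposited 1 table of array intensities on a linear scale, with 16637 FlyBase transcript identifiers and 24 columns, 1 per sample. The submitters' processing notes name RMA, a method that corrects background, quantile normalizes and summarises probes, and its version was not given in the sources used here. The deposited intensity values were whole numbers, and their medians differed from 1936 to 3289 between arrays, so that no common scale between arrays was present. No 2 columns were identical. Whether a background had been subtracted stays unknown.

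The values were taken to log2 and quantile normalized between all 24 arrays with limma version 3.58.1 in R version 4.3.3. A table already on a common scale had been assumed when the design was fixed before the data were examined. Quantile normalization, listed then as an alternative, therefore became the main setting, and the values without scaling became an added alternative. No transcript was filtered out. Arrays give no read depth, and the number of arrays limits the precision.

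A limma model with 1 mean for each of the 8 groups was fitted to all 24 arrays (16 residual degrees of freedom), followed by empirical Bayes moderation. Contrasts gave the mean stage change, the stage change per strain and the 6 strain differences averaged over both stages. Moderated F tests gave the interaction and the strain differences within a stage. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all 16637 transcripts, with a threshold of 0.05. A fold of 2 is a log2 change of 1. Errors beside fold changes are standard errors of the fit, and errors beside levels are standard deviations of 3 arrays. Shared replicate numbers were checked for pairing and were not used as a block in the main fit.

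Gene names came from a table of genes of assembly Release 6, which lists transcript identifiers only among synonyms. It held 44 of the 16637 identifiers. Of these, 16 belonged to 1 gene and were named (8 listed as they stand, 8 inside the name of an open reading frame: CG16974, CG31178, Fatp1, fend, HDAC3, NaPi-III, rdx and SuUR, of which a transcript with frames of 2 genes was not ruled out), 28 belonged to several genes and were not named, and 16593 were not listed. The design limited the test to named rows, which would have left 16, so all rows were tested instead. Among rows with 1 gene, the rule fixed beforehand named the 12 strongest mean stage changes in each direction with 1 sign in all strains. It also named the 3 strongest in each direction per strain, and per strain pair with 1 sign at both stages. To these it added the 5 widest strain ranges per stage and the 10 widest interactions. All had to pass the threshold. Of the 16, CG16974, HDAC3 and Wdr24 did not fall under this rule and were named only because a gene name could be given. The 4 transcripts given by identifier also lie outside that rule and were taken as the 2 strongest rises and the 2 strongest falls with 1 sign in all strains. None of the 31 gene lists fixed beforehand had a named member, so no list was tested. No coordinates are given, since no genome build was named in the sources used here.

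The fits were tested on simulated data with the real transcripts' means and their spreads pooled over groups, in which 200 transcripts were changed. Noise was drawn independently for each transcript and array. The simulation therefore did not cover the axis that held 54.7% of the real variation between replicates, nor groups of unequal spread. Nor did it cover quantile scaling where most transcripts change, so the shares below may not hold for the real data. For the mean stage change over 16637 transcripts, changes of 0.25, 0.5 and 1 on the log2 scale were recovered in 73.1%, 95.5% and 100% of cases. For the stage change in 1 strain (Oregon-R) the shares were 23.9%, 62.7% and 98.5%, with 8.21% false calls, and for the interaction with 1 strain changed 10.4%, 35.8% and 90.9%. The alternatives were median centring, no scaling, background correction by normexp with an offset of 50, leaving out the dimmest 30% or 50% of transcripts, an intensity trend with robust moderation, array weights, fits of the compared groups alone, the replicate number as a block, a threshold of 0.01, a 2-fold minimum, leaving out each array, leaving out Canton-S, leaving out 2 Zimbabwe-109 arrays, and a covariate for the main axis of variation between replicates.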

Results

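Whole-animal messenger RNA of Drosophila melanogaster was measured in 4 strains at 2 stages on either side of the start of metamorphosis. Oregon-R and Canton-S are long-kept laboratory wild-type stocks, and Samarkand and Zimbabwe-109 are wild-type stocks named after places. The late larva was a larva of the last instar before puparium formation, the moment when the larval cuticle becomes the pupal case. The prepupa was a white prepupa, an animal that had just formed its puparium. Each of the 8 strain-by-stage groups held 3 biological replicates, and each replicate was hybridised to 1 single-colour array, which gave 24 arrays. The series title places the arrays in a study of the evolution of microRNA expression at this transition, and the design text sets genotypes and developmental states against each other. Each array gave 1 intensity for each of 16637 FlyBase transcripts, and the median intensity per array ran from 1936 to 3289. The number of arrays limits the precision of every value below. A gene name could be given to 16 of the transcripts, and the rest are summarised as counts. For 8 of them (CG16974, CG31178, Fatp1, fend, HDAC3, NaPi-III, rdx and SuUR) the name rests on an open reading frame named after the transcript, and it was not checked whether that transcript also carries the frame of another gene.

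The first question was which transcripts differed between late larvae and prepupae when the 4 strains were averaged. Of the 16 named transcripts, 5 rose and 6 fell. The deepest fall was in Fatp1, a fatty acid transport protein, whose mean log2 intensity was 12.38 in larvae and 11.32 in prepupae, a change of -1.06 ± 0.07 on the log2 scale (SE, 12 arrays per stage, adjusted p = 1.76e-11), with the same sign in 4 of 4 strains. The transcript of alpha-Spec, which encodes alpha spectrin of the membrane skeleton, changed by -0.66 ± 0.12 (adjusted p = 6.48e-05; -1.02 with normexp). NaPi-III, a sodium-dependent phosphate transporter, changed by -0.43 ± 0.06 (adjusted p = 3.86e-06; -0.27 without Canton-S). Smaller falls were found in kis, a chromatin remodeller (-0.21 ± 0.06), mio, a component of a complex in nutrient signalling (-0.17 ± 0.03), and CG16974 (-0.14 ± 0.05).

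The strongest named rise was in CG31178, at 0.50 ± 0.03 (SE, adjusted p = 4.07e-11). It was followed by rdx, an adaptor of a ubiquitin ligase (0.31 ± 0.03), and His4r, a replacement histone H4 (0.30 ± 0.04). The transcript of sle, a nucleolar protein, rose by 0.19 ± 0.03 (0.125 without Canton-S), and that of SuUR, which acts on the replication of polytene chromosomes, by 0.11 ± 0.04. All of these kept 1 sign in 4 of 4 strains, except CG16974, which kept it in 3. The other 5 named transcripts did not pass the test. Their mean changes were 0.06 ± 0.05 for fend, 0.01 ± 0.04 for Uba1, the ubiquitin-activating enzyme, -0.01 ± 0.03 for LanA, a laminin chain, -0.06 ± 0.03 for Wdr24, which acts in the same complex as mio, and -0.07 ± 0.06 for HDAC3, a histone deacetylase. Uba1 had a change below 0 under 4 of the other settings tried and with any 1 of 3 arrays left out. With the arrays left unscaled, CG16974 (-0.19), mio (-0.17), rdx (0.20), sle (0.07) and SuUR (0.06) no longer passed the threshold. Nor did sle (0.08, adjusted p = 0.181) and SuUR (0.07, adjusted p = 0.089) with median centring, SuUR (adjusted p = 0.1) and CG16974 (adjusted p = 0.0522) without Canton-S, or kis (-0.16, adjusted p = 0.0638) and CG16974 (-0.08, adjusted p = 0.208) with a fixed replicate block.

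**Figure D1:**
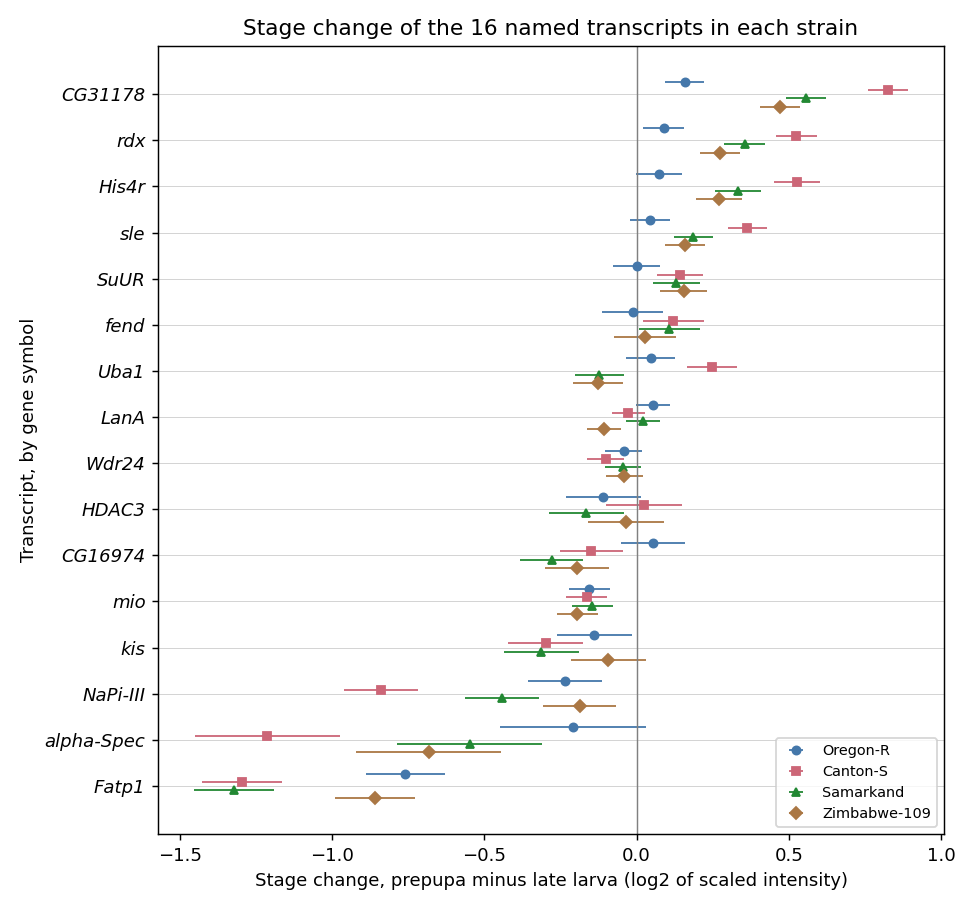
Stage change (prepupa minus late larva, log2 of scaled intensity, horizontal axis) of the 16 named transcripts (vertical axis, ordered by their mean change) in each of the 4 strains; points are means of 3 against 3 arrays and bars are the standard error of the fit. Fatp1 lies furthest to the left, between -1.32 and -0.76, and CG31178 furthest to the right, between 0.16 and 0.83, with Oregon-R nearest to 0 in both.

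Across all 16637 transcripts, 11887 passed the test of the mean stage change, 7492 of them higher and 4395 lower in prepupae. Large changes were more often falls, since 502 transcripts fell at least 2-fold and 144 rose at least 2-fold (812 and 241 with normexp background correction). The transcripts that fell at least 2-fold had a median log2 intensity of 12.66 in larvae and 11.08 in prepupae, and those that rose at least 2-fold went from 11.52 to 13.12. The split between higher and lower calls depended on the scaling of the arrays. It was 63.0% higher in the main fit, and 51.9% higher, with 3143 higher and 2911 lower, when the arrays were left unscaled.

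The 2 strongest rises and the 2 strongest falls are given by identifier, since no gene name could be attached to them. FBtr0075740 rose by 4.06 ± 0.20 on the log2 scale (SE, adjusted p = 7.3e-13), from 10.64 to 14.70, which is 16.7-fold. FBtr0076956 rose by 3.50 ± 0.19, or 11.3-fold (adjusted p = 1.67e-12). FBtr0089747 changed by -3.66 ± 0.21 (adjusted p = 6.45e-12) and FBtr0088763 by -3.47 ± 0.19 (adjusted p = 2.96e-12), from 14.41 to 10.94. With normexp background correction these changes were 5.12, 4.02, -4.69 and -4.31 in the same order, so the folds depend on the treatment of background. The spread between replicates of these transcripts was uneven. FBtr0075740 stood at 10.35 ± 0.05 (SD, n = 3) in Samarkand larvae and at 11.28 ± 1.55 (SD, n = 3) in Zimbabwe-109 larvae, where replicates 1, 3 and 4 read 10.34, 10.43 and 13.07. FBtr0089747 stood at 11.27 ± 1.55 (SD, n = 3) in Zimbabwe-109 prepupae, where replicates 2, 3 and 4 read 13.05, 10.42 and 10.33.

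**Figure D2:**
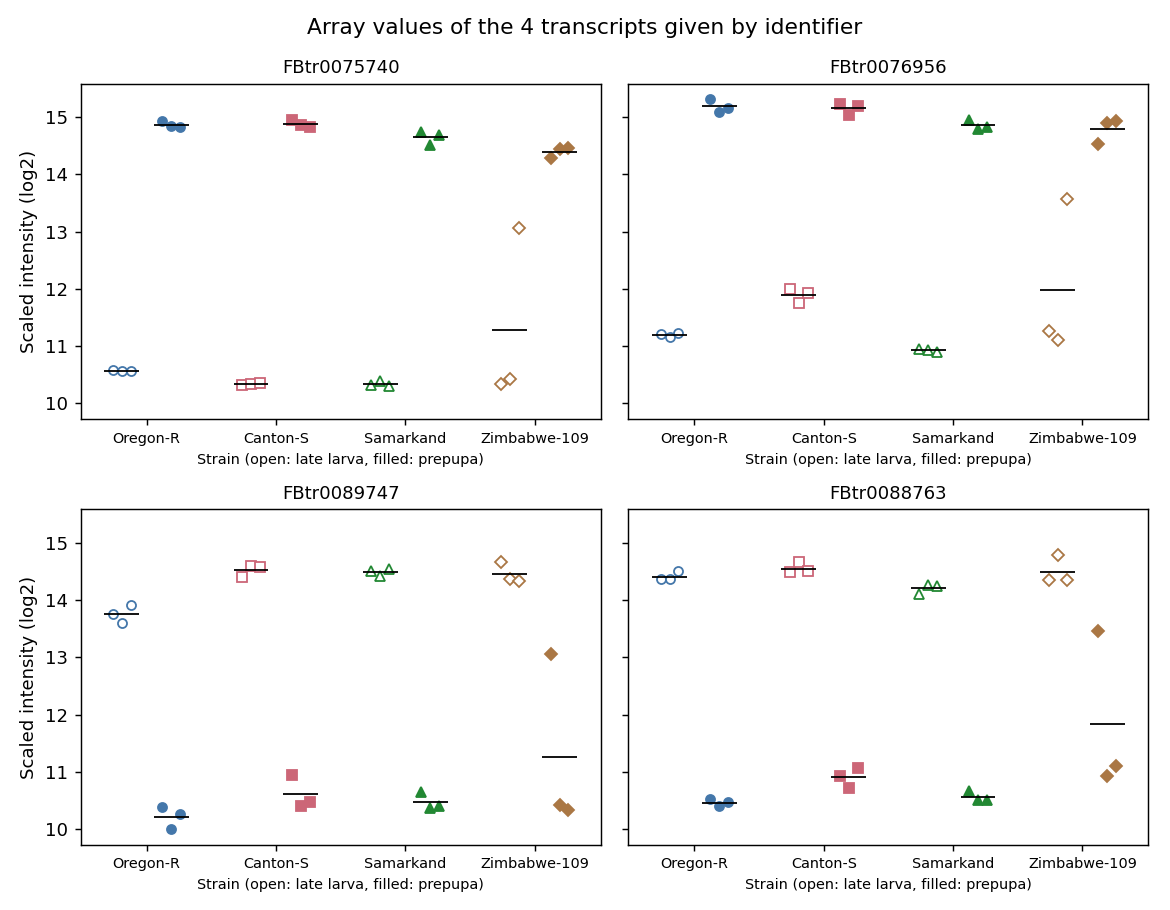
Scaled intensity (log2, vertical axis) of the 4 transcripts on each of the 24 arrays, by strain (horizontal axis); open symbols are late larvae, filled symbols prepupae, and short lines the means of 3 arrays. Of the Zimbabwe-109 arrays, 1 larval array lies above its group for both rising transcripts (13.07 for FBtr0075740) and 1 prepupal array above its group for both falling transcripts (13.05 for FBtr0089747).

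The stage change was then tested within each strain. Fatp1 fell in each of the 4 strains, with changes of -0.76 in Oregon-R, -1.30 in Canton-S, -1.32 in Samarkand and -0.86 in Zimbabwe-109, each with an SE of 0.13. CG31178, His4r and rdx rose in Canton-S, Samarkand and Zimbabwe-109, and in Oregon-R their changes of 0.16, 0.07 and 0.09 did not pass the threshold. The alpha-Spec transcript fell in Canton-S (-1.21 ± 0.24) and in Zimbabwe-109 (-0.68 ± 0.24), while its changes of -0.55 in Samarkand and -0.21 in Oregon-R did not pass. Its replicates were far apart in Samarkand prepupae (SD 0.81, n = 3). The decline of NaPi-III passed in Canton-S (-0.84 ± 0.12) and Samarkand (-0.44 ± 0.12). Without scaling, the rises of CG31178, His4r and rdx passed in Canton-S alone, and the changes of alpha-Spec in Zimbabwe-109 (adjusted p = 0.0847) and of NaPi-III in Samarkand (adjusted p = 0.157) did not pass. With median centring rdx did not pass in Samarkand (adjusted p = 0.0568), nor rdx and His4r in Zimbabwe-109 (adjusted p = 0.102 and 0.104), and with 2 Zimbabwe-109 arrays left out alpha-Spec (adjusted p = 0.067) and His4r (adjusted p = 0.0504) did not pass in that strain.

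The number of transcripts called between stages was 2781 in Oregon-R (1284 higher, 1497 lower), 9439 in Canton-S (5584 higher, 3855 lower), 8451 in Samarkand (5158 higher, 3293 lower) and 4928 in Zimbabwe-109 (2708 higher, 2220 lower). A common set changed everywhere. In all 4 strains 820 transcripts were higher and 1046 lower in prepupae, and of them 77 were at least 2-fold higher and 200 at least 2-fold lower in each strain. Independent lists of these sizes would share 21.8 and 9.16. The tests of the 4 strains shared 1 estimate of the spread per transcript and 1 scaling, which favours shared calls, so these values are a low reference. Opposite calls in different strains were found for 139 transcripts. Across transcripts, which are not independent replicates, the stage changes of 2 strains correlated between r = 0.77 (Oregon-R and Canton-S) and r = 0.91 (Canton-S and Samarkand, Samarkand and Zimbabwe-109). Without scaling the counts were lower, with 294 higher and 546 lower in Oregon-R, 4077 and 1996 in Canton-S, 481 and 1687 in Samarkand, and 182 and 1133 in Zimbabwe-109. The larger direction thus turned to falls in Samarkand and Zimbabwe-109 and stayed the same in Oregon-R and Canton-S. With median centring it turned in Zimbabwe-109 (1643 higher, 2001 lower) and in no other strain. With 1 larval and 1 prepupal array of Zimbabwe-109 left out, those that stood apart in the plot of array values, 4779 transcripts were called in that strain. A fixed replicate block gave 3093 and a fit of its arrays alone 2849, both with fewer residual degrees of freedom.

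**Figure D3:**
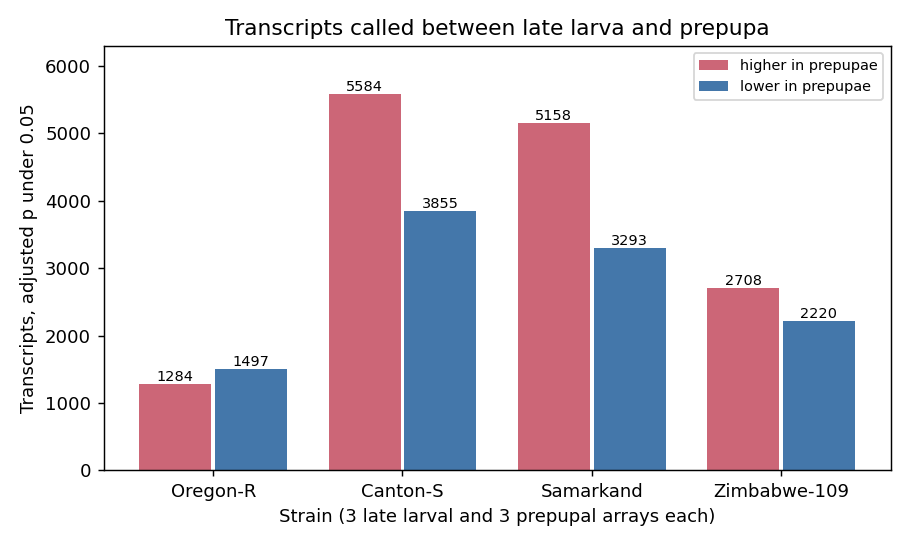
Number of transcripts called between late larvae and prepupae at an adjusted p under 0.05 (vertical axis) in each strain (horizontal axis), higher (left bars) and lower (right bars) in prepupae. Canton-S has the most calls (5584 higher, 3855 lower) and Oregon-R the fewest (1284 higher, 1497 lower).

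Whether the stage change itself differed among strains was tested with an interaction term. Among the named transcripts 5 passed: CG31178, Fatp1, His4r, NaPi-III and rdx. CG31178 rose by 0.83 ± 0.07 in Canton-S against 0.16 ± 0.07 in Oregon-R (interaction adjusted p = 0.000194). For rdx the changes were 0.52 and 0.09 in those strains (adjusted p = 0.0115), and for His4r 0.53 and 0.07 (adjusted p = 0.0229). NaPi-III changed by -0.84 in Canton-S and by -0.19 in Zimbabwe-109 (adjusted p = 0.0237), and Fatp1 by -1.32 in Samarkand and -0.76 in Oregon-R (adjusted p = 0.0446). In late larvae of Oregon-R, the 3 of these that rose stood higher than in the other strains and the 2 that fell stood lower. In prepupae too CG31178 was highest and NaPi-III and Fatp1 lowest in Oregon-R, while His4r was highest in Zimbabwe-109 and rdx in Canton-S. Adjusted over the 16 named transcripts alone, 7 passed. Of the 5, only CG31178 passed without scaling, rdx did not pass with median centring (adjusted p = 0.325), Fatp1 and NaPi-III did not with normexp (adjusted p = 0.117 and 0.132), and Fatp1 did not with the 2 Zimbabwe-109 arrays left out (adjusted p = 0.0718). Over all transcripts 3922 passed the interaction test, and in 605 of them the 4 stage changes spanned at least 1 on the log2 scale (937 with median centring, 1171 with normexp). The count was 1064 without scaling, 1587 without Canton-S and 1926 with a fixed replicate block, a fit with fewer residual degrees of freedom. It was 15976 with array weights, whose fit did not converge and put much of the weight on 3 arrays.

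The strains were compared within each stage, which sets the genotypes of the series against each other. RNA of different strains was extracted independently, so a strain difference here and below cannot be told apart from a difference in extraction. In late larvae 12 of the 16 named transcripts differed among strains, in prepupae 10 (9 when adjusted over the named transcripts alone), and 9 differed at both stages. These counts were 8, 5 and 4 without scaling, 14, 13 and 12 with median centring, and 11, 7 and 6 with the 2 Zimbabwe-109 arrays left out. NaPi-III differed most. It stood at 12.59 ± 0.05 (SD, n = 3) in Canton-S larvae and at 11.11 ± 0.03 (SD, n = 3) in Oregon-R larvae (adjusted p = 9.99e-09 over the 4 strains), and at 11.75 ± 0.21 and 10.87 ± 0.20 in their prepupae (adjusted p = 1.51e-05). SuUR was highest in Samarkand at both stages, with 12.57 ± 0.08 in larvae and 12.70 ± 0.09 in prepupae, and lowest in Oregon-R, with 12.13 at both (adjusted p = 4.22e-05 and 7.7e-06). The strain range of fend was 0.38 in larvae and 0.51 in prepupae, Canton-S being highest and Oregon-R lowest at both. Fatp1 spanned 0.91 in larvae, from Oregon-R to Canton-S (adjusted p = 1.25e-05), and its range of 0.38 in prepupae did not pass (adjusted p = 0.0624). The alpha-Spec transcript likewise passed in larvae (range 1.06, adjusted p = 0.0021) and not in prepupae (adjusted p = 0.156). Uba1 passed in prepupae (range 0.50, adjusted p = 0.00016) and not in larvae (adjusted p = 0.237). Without scaling fend passed at neither stage (adjusted p = 0.573 and 0.662), and with median centring it did not pass in larvae (adjusted p = 0.16). Prepupal Fatp1 passed with median centring (adjusted p = 0.0313) and normexp (adjusted p = 0.0382), and larval Uba1 with median centring (adjusted p = 4.67e-07) and no scaling (adjusted p = 0.0333).

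Over all transcripts, 12824 differed among strains in late larvae and 11298 in prepupae. The range among strain means reached 1 on the log2 scale in 1045 of those in larvae and 432 of those in prepupae (2876 and 1620 with normexp). The prepupal count was 4249 without scaling and 6338 without Canton-S. The Canton-S arrays had a wider distribution than the rest as deposited, with an interquartile range of 1.56 ± 0.08 on the log2 scale (SD, n = 6) against 1.24 ± 0.03 in Oregon-R, 1.23 ± 0.05 in Samarkand and 1.24 ± 0.05 in Zimbabwe-109.

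Pairs of strains were compared on the mean of both stages. NaPi-III was higher in Canton-S than in Oregon-R by 1.18 ± 0.09, than in Samarkand by 0.98 ± 0.09 and than in Zimbabwe-109 by 0.94 ± 0.09 (adjusted p = 7.45e-10, 1.29e-08 and 1.29e-08). Samarkand exceeded Oregon-R in SuUR by 0.51 ± 0.05 (adjusted p = 3.69e-07). Levels of sle were lower in Samarkand than in Oregon-R and Zimbabwe-109, with means of 13.11, 13.48 and 13.49. CG31178 stood at 12.06 in Oregon-R and between 11.68 and 11.74 in the other 3 strains, and LanA at 13.05 in Oregon-R and between 13.19 and 13.24 in the others. His4r was lowest in Canton-S (12.62) and highest in Zimbabwe-109 (12.97). Without scaling, sle passed in neither of its 2 pairs (adjusted p = 0.305 and 0.126), nor did CG31178 and LanA between Oregon-R and Samarkand (adjusted p = 0.355 and 0.0589) or Zimbabwe-109 (adjusted p = 0.056 and 0.554). His4r did not differ past the threshold between Canton-S and Zimbabwe-109 without scaling (adjusted p = 0.435) or with median centring (adjusted p = 0.234), nor LanA between Oregon-R and Zimbabwe-109 with the 2 arrays left out (adjusted p = 0.0527).

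The number of transcripts that differed was 11412 between Oregon-R and Canton-S, 10413 between Canton-S and Samarkand and 11696 between Canton-S and Zimbabwe-109. The pairs without Canton-S gave 6035 for Oregon-R and Samarkand, 6859 for Oregon-R and Zimbabwe-109 and 7298 for Samarkand and Zimbabwe-109. Differences of at least 2-fold numbered 182, 100 and 192 in the pairs with Canton-S and 74, 83 and 96 in the others, in the same order. These counts depended on the processing, with 815, 475 and 991 in the pairs with Canton-S under normexp, and 393, 153 and 421 under median centring. The others gave 257 for Oregon-R and Samarkand, 308 for Samarkand and Zimbabwe-109, and 162 higher and 147 lower in Zimbabwe-109 than in Oregon-R under normexp. Of the called transcripts, between 91.4% (Oregon-R and Canton-S) and 97.1% (Samarkand and Zimbabwe-109) had the same sign in larvae and prepupae. Calls were made on the mean of both stages, which itself favours equal signs. Over all transcripts, larval and prepupal differences correlated between r = 0.52 (Oregon-R and Samarkand) and r = 0.75 (Canton-S and Samarkand). In the main fit between 46.1% and 52.3% of the calls were higher in the second-named strain of a pair. Without scaling those shares were 31.8% for Oregon-R and Canton-S, 82.7% for Oregon-R and Samarkand, 55.2% for Oregon-R and Zimbabwe-109, 82.9% for Canton-S and Samarkand, 67.8% for Canton-S and Zimbabwe-109 and 24.7% for Samarkand and Zimbabwe-109.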

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

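The tests on the 2 Zimbabwe-109 arrays, on unscaled arrays and on prepupal RNA in Oregon-R larvae were chosen only after the values had been seen, and the test of brightness on the 2 arrays replaced a first one that had come out the other way. The test on 3 replicate axes was added late, before its own value had been seen, and the other tests in this part were set before. The stage change differed among strains by an interaction test in 3922 transcripts. Among the named ones, the 4 stage changes spanned 0.669 on the log2 scale for CG31178, 0.653 for NaPi-III, 0.564 for Fatp1, 0.451 for His4r and 0.436 for rdx. These are differences between groups under 1 contrast, and the count depended on the processing, as the next part gives.

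Strain differences among late larvae followed the stage change to an extent that varied by pair: across transcripts, the larval difference (second strain minus first) correlated with the stage change of the other 2 strains, which share no arrays with it, at r = -0.59 for Oregon-R and Canton-S, -0.5575 for Oregon-R and Samarkand, -0.21 for Oregon-R and Zimbabwe-109, 0.21 for Canton-S and Samarkand, 0.44 for Canton-S and Zimbabwe-109 and 0.36 for Samarkand and Zimbabwe-109 (prepupal differences between -0.19 and 0.09). Oregon-R and Samarkand were the pair taken for the tests after these values had been seen. There r was -0.5575 with quantile scaling, which makes the distributions equal, and -0.5725 without it. Since 1 factor per array leaves r as it is, median centring was no further test. As deposited, the arrays of these 2 strains already had much the same spread (mean interquartile range 1.24 and 1.23 on the log2 scale). Scaling could therefore change little here, and whether a different distribution of the arrays is a cause was not decided. In Canton-S and Samarkand, with the wider Canton-S arrays, r was 0.21 with quantile scaling and 0.36 without. The main axis of variation between replicates is argued against as the whole cause in Oregon-R and Samarkand, since taking it out left r = -0.5399. Variation along the first 3 replicate axes together cannot be told apart from the pattern, since they held 60.6% of the stage change itself, over the 10% set for the test. Taking them out left r = -0.2818 in this pair and -0.24, 0.02, -0.02, 0.18 and 0.25 in the other pairs in the order above. Prepupal RNA in the Oregon-R larval samples is argued against too: over 33 transcripts that rose at least 4-fold in the other strains, Oregon-R larvae stood at a median of 1.33% of the way to the prepupal level (quartiles 0.26% and 5.46%). A more advanced developmental age of the Oregon-R larvae may account for the pattern, because transcripts that rise (slope -0.243) and that fall (slope -0.393) were both shifted towards the prepupal level, an outcome named before these 2 slopes, though after the slope over all transcripts, had been seen; against Zimbabwe-109 the rising transcripts gave a slope of 0.0093, and between Canton-S and Samarkand -0.0626, against the sign of their falling transcripts (0.0972), so the shift was not found in every pair. The strong risers, at a median of 1.33% of the way, had moved little towards the prepupal level in Oregon-R larvae. That small share bears on a more advanced age as it does on prepupal RNA. A heritable difference between the strains in the timing of expression stays open and was not tested.

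Single arrays of Zimbabwe-109 lay between the stages, 1 larval (replicate 4) and 1 prepupal (replicate 2). On the larval array, 35 transcripts that rose at least 4-fold in the other 3 strains stood at a median of 24.4% of the way from the other larval arrays to the prepupal ones (quartiles 19.9% and 32.5%), where the highest of the other 11 larval arrays gave 0.95%, and on the prepupal array 113 falling transcripts stood at 22.96% of the way back, where the highest of the other 11 prepupal arrays gave 1.06%. Brightness of the arrays was not excluded by the first test, in which the smaller median fold over the group with no scaling (1.45) lay below the largest ratio of array medians (1.70), but that fold is lowered on a dim array, and the second test argues against it: 1 factor per array would move rising and falling transcripts alike, and with no scaling the lowest of the 4 median shares was 12.1% towards the other stage. RNA or animals of the other stage in these 2 samples is a candidate explanation, since the median shares of rising and falling transcripts both lay towards the other stage on both arrays, at shares above 5% that none of the other 22 arrays showed in both; the second class is weaker evidence, with 11.4% for rising transcripts on the prepupal array (quartiles -5.5% and 18.1%; 6.64% on the highest other) and 15.1% for falling ones on the larval array (quartiles 8.05% and 23.2%; 15.05% on Oregon-R larval replicate 3). No test here separates animals that were ahead or behind in the pool from RNA that was joined later, or from an intermediate age of all animals.

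A smaller set of transcripts set 1 strain apart by at least 2-fold from each of the others at both stages: 3 for Oregon-R, 8 for Canton-S, 10 for Samarkand and 12 for Zimbabwe-109. A probe mismatch or a deletion would lower the strain set apart, and 54.5% of the 33 transcripts were lower, with an exact 95% binomial interval from 36.4% to 71.9%, so that this explanation cannot be told apart from a change in level by direction alone; the number of transcripts keeps it open. In Zimbabwe-109, 9 were higher and 3 lower, and in Samarkand 2 were higher and 8 lower.

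Other splits of the same samples were counted for each comparison. For the mean stage change, 1 of 100 splits (stage labels shuffled within strain, the real one included) gave as many calls, with 7492 higher and 4395 lower against at most 2870 in either direction otherwise. This share lies under 0.05 and argues against a chance split, though 1 of 100 is the smallest share that 100 splits can give. The same holds, at 1 of 100 each, for the interaction (3922 against at most 714, with residuals of the additive model shuffled over the arrays), the strains in larvae (12824 against 8404) and the strains in prepupae (11298 against 8043). It also holds at 1 of 100 for Oregon-R and Canton-S (11412 against 8984), Oregon-R and Samarkand (6035 against 4630), Oregon-R and Zimbabwe-109 (6859 against 5524), Canton-S and Samarkand (10413 against 6841), Canton-S and Zimbabwe-109 (11696 against 7872) and Samarkand and Zimbabwe-109 (7298 against 3379). In the comparisons of strains the highest other count was a large part of the real one, so the size of those counts alone is weak evidence. Within 1 strain the 6 arrays make 10 splits, too few for a share under 0.05; the real counts were 2781 in Oregon-R, 9439 in Canton-S, 8451 in Samarkand and 4928 in Zimbabwe-109, and the highest other counts 0, 4, 0 and 1.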

How the results depend on the processing

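No scaling, normexp, leaving out Canton-S, leaving out the 2 Zimbabwe-109 arrays, adjustment over the named transcripts alone and the covariate were chosen after seeing the data; the rest were set before. In this part stage counts are given for Oregon-R, Canton-S, Samarkand and Zimbabwe-109 in that order. Over the settings that keep all arrays or leave out a strain or the 2 arrays, 152 of 210 counts of transcripts stayed within 1.5 times the main count. Leaving out each array in turn left all 360 counts within it. Median centring, normexp with quantile scaling, the dimmest 30% left out, the intensity trend, and the 2 Zimbabwe-109 arrays left out moved no count of called transcripts by over 1.5 times. The counts at 2-fold or more were less stable: normexp moved all 15 of them, median centring and the dimmest 30% left out 5 each, no scaling 3, and the trend and the 2 arrays left out 0. With normexp they were 687, 2006, 1367 and 820 between stages, and the report gives the others. Median centring gave 1608 among strains in larvae, and no scaling 1865 among strains in larvae, 239 for Canton-S and Samarkand, and 187 higher and 122 lower in Zimbabwe-109 than in Canton-S. With the dimmest 30% left out, 5 pairs gave between 47 and 123.

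Without scaling, the mean stage change gave 3143 higher and 2911 lower, the stages gave 840, 6073, 2168 and 1315, the interaction 1064, the strains in prepupae 4249, Oregon-R and Samarkand 1562, Oregon-R and Zimbabwe-109 1403, and Samarkand and Zimbabwe-109 1933. The cause was not tested.

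With the dimmest 50% left out, fewer transcripts were tested: 4142 higher and 2353 lower, 5350 in Canton-S and 5188 in Samarkand between stages, 2399 for the interaction, 6521 and 5870 among strains in larvae and prepupae, and for pairs 5813 (Oregon-R and Canton-S), 3214 (Oregon-R and Samarkand), 3417 (Oregon-R and Zimbabwe-109), 5122 (Canton-S and Samarkand), 5882 (Canton-S and Zimbabwe-109) and 3623 (Samarkand and Zimbabwe-109). With a 2-fold minimum the counts were 144 higher and 502 lower, 428, 1160, 844 and 494 between stages, 605 for the interaction, 1045 and 432 among strains, and 182, 74, 83, 100, 192 and 96 for the pairs in that order. An adjusted p under 0.01 gave 5589 in Samarkand, 3158 in Zimbabwe-109 and 2431 for the interaction.

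Array weights gave 11983 in Oregon-R, 14291 in Samarkand, 15398 in Zimbabwe-109, 15976 for the interaction, and 12905, 14397 and 14155 for Oregon-R and Samarkand, Oregon-R and Zimbabwe-109, and Samarkand and Zimbabwe-109. The estimated weights ran from 0.0622 to 1153 and their fit did not converge, with 3 arrays above 10, so that these counts rest on few arrays, 1 of them Zimbabwe-109 larval replicate 4 (weight 173.4), which lay between the stages. The covariate was the main axis of the same residuals, which lowers the residual spread by construction, so its gains are no support; the counts were 7220 in Oregon-R, 8735 in Zimbabwe-109, 9237 for the interaction and 9124 for Oregon-R and Samarkand. Leaving out Canton-S gave 1587 for the interaction and 6338 among strains in prepupae, with 1 strain fewer. A fit of the Zimbabwe-109 arrays alone, with fewer samples, gave 2849.

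The replicate numbers did not pair the samples: 5 of 9 same-numbered pairs correlated above 0.1 in their deviations, and the lowest value was -0.632. With a fixed replicate block, 3093 transcripts were called in Zimbabwe-109 and 1926 for the interaction, and kis and CG16974 no longer passed; the random replicate block changed no call of a named transcript and moved no count by over 1.5 times.

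In the mean stage change, the named transcripts and the 4 given by identifier kept their direction and side of the threshold in 249 of 271 values under other settings and in 476 of 480 with 1 array left out. In the tests within strains, among strains and of the interaction, the named transcripts kept their side in 1408 of 1651 values under 8 settings, with 96 calls lost (59 without scaling, 15 with the 2 arrays left out, 12 with median centring, 7 with normexp) and 147 gained (77 with array weights, 38 with the covariate, 21 with median centring); no other setting was run for these. Uba1, which passed no test of the mean stage change in the main fit, changed sign to -0.1358 without scaling, -0.129 with median centring (adjusted p = 0.0144), -0.0116 with array weights and -0.0644 without Canton-S, and ran from -0.013 to 0.0342 with 1 array left out. LanA passed with median centring (-0.14), while sle and SuUR no longer did; SuUR and CG16974 did not pass without Canton-S, nor under a threshold of 0.01. With array weights fend (adjusted p = 0.0177) and HDAC3 (adjusted p = 0.00559) passed. Leaving out Zimbabwe-109 late larval replicate 3 brought Wdr24 past the threshold (-0.07, adjusted p = 0.0175), as did array weights, and the range of its adjusted p over the settings was 0.00122 to 0.591. Rows of 1 gene were not averaged and camera was not run, since each row was 1 transcript and no list had a named member. Low intensities near the array minimum, between 156 and 252, limit what can be said of weak transcripts.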

Other observations

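Of the named transcripts, 3 passed the test of strain differences at neither stage: kis, HDAC3 and Wdr24. The ranges among strain means were 0.30 in larvae and 0.14 in prepupae for kis, 0.17 and 0.28 for HDAC3, and 0.16 and 0.10 for Wdr24, against 1.48 and 0.88 for NaPi-III. On the mean of both stages, single pairs of strains still differed. The level of kis was 12.56 in Canton-S and 12.36 in Zimbabwe-109 (adjusted p = 0.0457), that of HDAC3 11.48 and 11.27 in the same strains (adjusted p = 0.0471), and that of Wdr24 11.36 in Oregon-R and 11.49 in Canton-S (adjusted p = 0.0104). With median centring kis passed at both stages (adjusted p = 2.99e-05 and 0.0125) and Wdr24 in larvae (adjusted p = 0.0227). Canton-S and Zimbabwe-109 did not differ past the threshold in kis or HDAC3 with 2 Zimbabwe-109 arrays left out (adjusted p = 0.113 and 0.107) or with normexp (adjusted p = 0.0523 and 0.0555), nor in HDAC3 without scaling (adjusted p = 0.841). The pair of Wdr24 did not pass without scaling (adjusted p = 0.907).

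Replicates of late larvae lay closer together than those of prepupae in 3 strains. The median SD over transcripts was 0.040 in larvae and 0.114 in prepupae of Oregon-R, 0.066 and 0.120 in Canton-S, and 0.049 and 0.077 in Samarkand. In Zimbabwe-109 it was 0.117 in larvae and 0.081 in prepupae. A single axis held 54.7% of the variation between replicates within groups, and its loadings correlated with the mean stage change at r = -0.22 across transcripts. The next 2 axes held 12.35% and 6.2% and correlated with it at r = -0.54 and r = -0.52.

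In larvae the strain differences were wider than in prepupae for 5 of the 6 pairs. The SD of the difference over transcripts was 0.48 in larvae and 0.32 in prepupae for Oregon-R and Canton-S, and 0.33 and 0.35 for Canton-S and Samarkand, the pair that ran the other way.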
